A study of Arabidopsis thaliana with 6 samples.

How the data were processed

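Total RNA from seeds of 2 groups, wild type and anac089-2, with 3 biological replicates each, was labelled with biotin in 1 cycle and hybridised to Affymetrix ATH1 arrays, per the labels' protocols and the probe table. The authors deposited log2 expression values per probe set with 2 decimals, normalised with robust multi-array averaging (RMA), per the submitters' processing notes. The same notes name limma. Versions, the array definition file and the settings are not given in the sources used here. The authors also deposited a comparison table with group means and log2 fold changes, a signed fold change, and limma p-values and FDR values, per the file headers. Its log2 fold changes differed from those computed here by at most 0.013. A few p-value cells of that table had lost their decimal point and were read as 1. Further columns of per-array values in that table, 6 in number, were not used.

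Each of 22746 probe sets was tested, after 64 control probe sets were set aside, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 6 arrays, 2 groups, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are anac089-2 minus wild type throughout. SEs are those of the moderated test. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so no such test is reported. Signal over background is not given in the sources used here, and only the number of arrays is taken as the limit of precision.

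Gene names came from the probe table made from the platform annotation, which gives 1 gene symbol for 13513 probe sets and several for 503, and does not list 8730. A further 158 probe sets of list genes were named from the authors' own title column. Locus identifiers were found for 13436 probe sets through Entrez identifiers in the RefSeq annotation of assembly TAIR10.1. Probe sets that neither source names are given by the authors' title.

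Before the data were examined, 23 gene lists and the rule for genes named in the text were fixed. The rule takes ANAC089, then the 15 higher and the 15 lower probe sets of 1 gene with the largest change among those past the threshold whose groups do not overlap. For each list it takes up to 4 members past the threshold with the largest change, or, where none passes, the 2 with the largest change, as values. The lists are ABA perception and core signalling, ABA-responsive genes, ABA metabolism, LEA proteins, storage and oil body proteins, maturation and dormancy regulators, gibberellin, germination cell wall, redox and nitric oxide, unfolded protein response, membrane-bound NAC factors, sugar and energy signalling, oil mobilisation, cell cycle, photosynthesis and greening, heat shock proteins, pathogen defence, auxin, ethylene, flavonoids, and markers of endosperm, seed coat and embryo. Of 361 list genes 210 were measured under a name found here. A gene with several probe sets counted once, by the brightest. Lists with at least 3 measured members, 22 of 23, were tested with camera (preset inter-gene correlation 0.01, adjusted over the 22 lists), with camera and an estimated correlation, and with fry. Fry asks whether a list's genes move on balance one way without comparing them with other genes. It gave adjusted p-values of 0.0210 for ABA metabolism and for germination cell wall, and 0.0613 for LEA proteins, storage proteins and ABA-responsive genes.

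After the data were examined, camera was also run on 980 words and word pairs of the authors' titles that mark 15 to 600 probe sets. Some narrower wordings, such as 60S ribosomal, were picked from these by hand. Cyclic loess across arrays was added as another normalization for the same reason.

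The alternatives tried were a second quantile normalization, centring each array on its median, leaving out the dimmest 40% of probe sets, an intensity trend or robust estimate of the spread, array weights, the replicate number as a block, no moderation of the spread, the authors' deposited statistics, stricter thresholds, the mean over a gene's probe sets, and leaving out each array in turn. No pair of arrays held identical values throughout.

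The procedure was tested on simulated data made for anac089-2 against wild type over 22746 probe sets, of which 200 were changed. Of those changed by 0.5, 1 and 2 on the log2 scale, 3 of 67, 37 of 67 and 61 of 66 were recovered, 0 in the wrong direction, with 10 unchanged probe sets called. With nothing changed, 0 probe sets, 0 lists and 0 title words passed. The simulated probe sets varied independently of each other. The simulation therefore does not show how list and title-word tests behave when genes are correlated. Plots were drawn with matplotlib 3.10.9.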

Results

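Gene expression was measured in seeds of Arabidopsis thaliana carrying the anac089-2 mutation and in wild-type seeds of the parent accession Columbia-0 (Col-0). ANAC089 belongs to the NAC family of plant transcription factors and carries a membrane anchor. Seeds had imbibed water for 3 days at 4 °C in the dark and were then kept in light at 22 °C for 3 h with 5 µM abscisic acid (ABA), the hormone that holds back germination. The comparison asks which transcripts differ between anac089-2 and wild-type seeds in the presence of ABA. No seeds were kept without ABA, so a response to ABA was not measured. A changed response cannot be told apart from a difference that is there without ABA. Each group had 3 biological replicates, each on its own ATH1 array (Affymetrix), and 22746 probe sets other than controls were tested on the log2 scale. The number of arrays limits the precision of every value below. Array medians were between 3.97 and 4.01 on 5 arrays and 3.80 on wild-type replicate 3. That array also had the lowest mean correlation with its own group, 0.982 against 0.987 to 0.996 for the others.

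The mutated gene would be the first check of the labels, but no source used here pairs a probe set with ANAC089, so no probe set is analysed here under its name. The probe set that differed most between the groups carries the title of a no apical meristem (NAM) family protein in the authors' deposited table, a title that 83 probe sets share, and no source used here gives its gene. The NAC gene ANAC014 carries the same title, so whether this probe set measures ANAC089 itself or another gene cannot be told here. It is labelled by its probe set ID in the plot of the largest changes. Its log2 level was 9.53 ± 0.085 (SD, n = 3) in wild type and 4.17 ± 0.131 (SD, n = 3) in anac089-2, a fall of 41.0-fold (limma adjusted p = 4.38e-06). All 3 wild-type arrays, replicate 3 included at 9.59, lay more than 5 log2 units above all 3 mutant arrays.

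NIT4, a nitrilase that acts on beta-cyanoalanine in cyanide detoxification, fell 13.6-fold in anac089-2, with a log2 fold change of -3.77 ± 0.153 (SE, n = 3 per group, limma adjusted p = 3.29e-04). Levels of NIT4 (4.14) and of the NAM family probe set in anac089-2 were close to the array medians, and signal over background is not given in the sources used here, so both folds are those of the deposited values. AT4G39670, titled an expressed protein, fell by 3.32 on the log2 scale (SE 0.331), and AT3G46070, a C2H2 zinc finger protein, fell by 2.77 (SE 0.312). AOX1A, the mitochondrial alternative oxidase, fell by 2.19 (SE 0.287), and the beta-glucosidase gene BGLU28 fell by 2.38 (SE 0.209). SPE2, an arginine decarboxylase of polyamine synthesis, fell by 1.95 (SE 0.234), and the homeodomain-leucine zipper gene HAT22 fell by 2.05 (SE 0.181). The level of HAT22 in anac089-2 (3.88) was below the array medians of that group, so the same limit holds for it. The other probe sets among the 15 largest decreases were a kelch repeat F-box protein (-2.48), AT4G18950 (an ankyrin protein kinase, -2.32), AT2G32190 (-2.16), a putative beta-mannan endohydrolase (-2.15), AT2G41730 (-2.01, on a probe set of a type that shares probes with similar sequences), AT2G38900 (a potato inhibitor type protease inhibitor, -1.98) and the arabinogalactan protein gene AGP1 (-1.96). Limma adjusted p-values of the 15 decreases reached at most 0.0203.

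Among increases, AT2G35750, an expressed protein, rose 4.26-fold (log2 fold change 2.09 ± 0.156, SE, n = 3 per group, limma adjusted p = 0.00589). FAD3, the omega-3 fatty acid desaturase of the endoplasmic reticulum, rose 4.08-fold (2.03 ± 0.159, SE). EXPA1, an expansin that loosens cell walls, rose 3.33-fold (1.74 ± 0.208, SE), and SHD, the endoplasmic reticulum member of the HSP90 chaperone family, rose 3.01-fold (1.59 ± 0.282, SE). GDSL-motif lipase or hydrolase genes AT1G71250, AT3G14220 and AT5G14450 rose by log2 fold changes of 1.91, 1.80 and 1.79. The remaining genes of the 15 largest increases were AT5G52450, a MATE efflux protein (1.95), the putative N-acetyltransferase gene HLS1 (hookless1, 1.86), AT1G01300, an aspartyl protease (1.82), the cysteine synthase gene OAS5 (1.75), AT5G11420 (1.74), a leucine-rich repeat transmembrane kinase (1.64), the serine carboxypeptidase gene scpl29 (1.59) and the esterase or lipase gene AT2G39420 (1.58). Limma adjusted p-values of these 15 increases reached at most 0.0359.

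**Figure D1:**
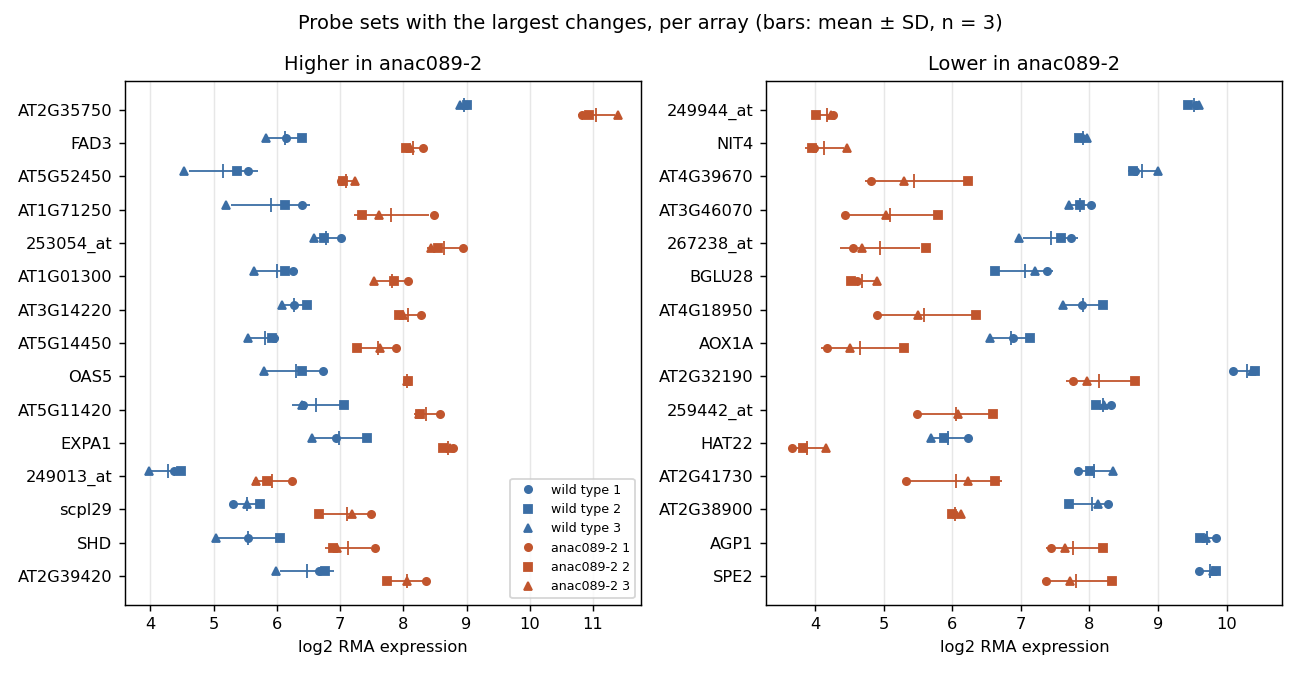
Log2 expression (horizontal axis) of the 15 most increased (left) and 15 most decreased (right) probe sets on each of the 6 arrays, wild type in blue and anac089-2 in red, with bars for the mean ± SD of 3 arrays. The groups do not overlap for any of the 30, and the NAM family probe set and NIT4, the top pair on the right, show the widest gaps, -5.36 and -3.77.

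Over all probe sets, 1120 differed between the groups at a limma adjusted p under 0.05, of which 669 were higher and 451 lower in anac089-2. The groups did not overlap for 5461 probe sets, or 24.0%, where chance gives 10%, and all 1120 were among them. The authors' deposited table holds 1121 probe sets at the same threshold, and 1115 of them passed here in the same direction. The count was 6 without anac089-2 replicate 1, 4 without replicate 3 and 470 without replicate 2, and 521 and 301 without wild-type replicates 1 and 2. Of the 30 genes named above, 3 stayed past the threshold without anac089-2 replicate 1 and 3 without replicate 3, while all 30 kept their direction; the NAM family probe set, NIT4 and AT2G35750 passed whichever array was left out.

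**Figure D2:**
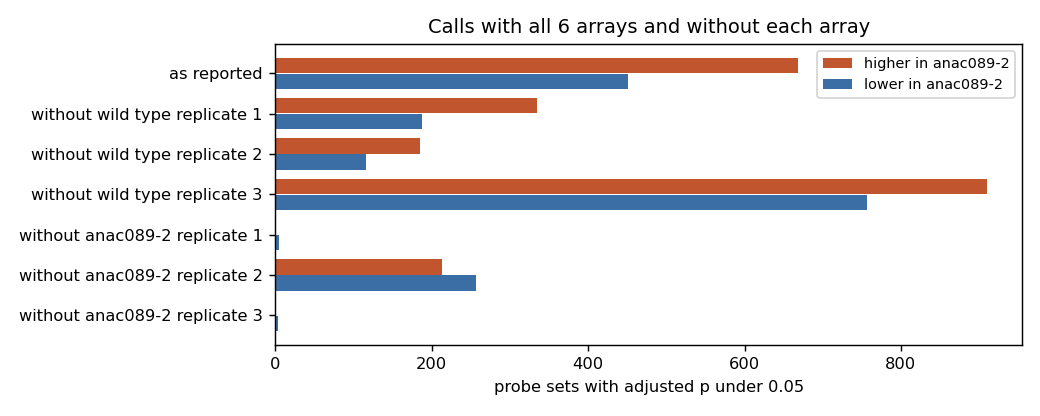
Number of probe sets with an adjusted p under 0.05 (horizontal axis), higher (red) and lower (blue) in anac089-2, with all 6 arrays and with each array left out. The total falls from 1120 to 6 and 4 without anac089-2 replicates 1 and 3, and is 1667 without wild-type replicate 3.

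The lists of desiccation protection genes and of seed storage genes were lower in anac089-2. Of 14 measured genes for late embryogenesis abundant (LEA) proteins, which protect dry tissue, 4 fell, 0 rose and 10 did not pass: AT3G22490 (-0.95 ± 0.210, SE), EM1 (-0.79 ± 0.141, SE), AT5G44310 (-0.75 ± 0.132, SE) and ECP63 (-0.69 ± 0.138, SE). Of 9 genes for storage and oil body proteins, 4 fell, 0 rose and 5 did not pass: the albumin genes SESA4 (-1.30 ± 0.148, SE), SESA2 (-0.92 ± 0.179, SE) and SESA1 (-0.77 ± 0.107, SE), and the cruciferin gene CRU2 (-0.66 ± 0.107, SE). Adjusted over the list alone, 6 LEA genes and 4 storage genes fell. Outside the LEA list, a probe set titled LEA3 family protein rose (1.47). Both lists shifted down as a whole (camera adjusted p = 7.09e-05 for LEA proteins and 1.45e-04 for storage proteins), and both had an adjusted p = 0.440 with an estimated correlation. Without wild-type replicate 3, whose levels of both lists were the highest of the 6 arrays, the camera adjusted p was 0.00407 for each.

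Textbook ABA-induced genes were lower as a list. RD29B (-1.09 ± 0.146, SE), EM1 (-0.79) and RD29A (-0.69 ± 0.111, SE) fell, while HIS1-3, a linker histone variant, rose (1.00 ± 0.205, SE). Of 17 measured members 4 fell, 1 rose and 12 did not pass, and adjusted over the list alone 5 fell and 1 rose. The list's camera adjusted p was 0.00214, with an adjusted p = 0.440 with an estimated correlation, and 0.0781 without wild-type replicate 3. The 5 measured genes of ABA metabolism were also lower as a list, with ABA1, the zeaxanthin epoxidase of ABA synthesis, falling by 0.70 (SE 0.125). All 5 measured members, of 15 listed, had negative values, 1 passed and 4 did not, and 2 fell when adjusted over the list alone. Wild-type levels of AAO3 (3.25), UGT71B6 (3.34) and BG1 (3.01) were below the array medians. No NCED or CYP707A gene of the list was measured under a name found here. This list gave a camera adjusted p of 0.00253, an adjusted p = 0.438 with an estimated correlation, and 0.00553 without wild-type replicate 3. Of 32 listed genes of ABA perception and core signalling, only 6 were measured under a name found here: ABI1, ABI2, ABI3, ABI4, ABF3 and ABF4. None of them passed (camera adjusted p = 0.710). No ABA receptor or SnRK2 kinase gene was among them, so perception itself was not tested. The largest values there were those of the transcription factor genes ABI4 (0.72, adjusted p = 0.0622) and ABI3 (0.50, adjusted p = 0.106), and both passed when adjusted over the list alone.

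The measured genes of the list for cell wall remodelling in germination were higher as a list in anac089-2. The expansin genes EXPA1 (1.74) and EXPA9 (0.43 ± 0.092, SE) rose, 8 of the 10 measured members did not pass, and all 10 had positive values. Adjusted over the list alone, 4 rose. The camera adjusted p was 0.00253, with an adjusted p = 0.438 with an estimated correlation, and it was 0.00407 without wild-type replicate 3. Leaving out the dimmest 40% of probe sets ended this call (0.167). Wild-type levels of EXPA9 (3.12), EXPA3 (3.15), XTH4 (3.51), XTH5 (3.57), EXPA2 (3.61) and XTH33 (3.62) were below the array medians. No endo-mannanase gene of the list was measured under a name found here. A probe set titled a putative beta-mannan endohydrolase, not counted in the list, was among the 15 largest decreases (-2.15). Gibberellin genes did not shift as a list (17 measured, 0 past the threshold, 2 adjusted over the list alone, camera adjusted p = 0.634). The DELLA gene GAI had 0.94 (adjusted p = 0.0523) and the F-box gene SLY1 0.91 (adjusted p = 0.0555).

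Genes titled as proteins of the cytosolic ribosome were higher in anac089-2. Of 115 probe sets titled 60S ribosomal, 75 rose and 1 fell, with a median log2 fold change of 0.72, and of 85 titled 40S ribosomal, 52 rose and 0 fell, with a median of 0.71. Examples are RPL12C (AT5G60670, 1.51 ± 0.185, SE), RPL36A (AT2G37600, 1.41 ± 0.168, SE), RPS12A (AT1G15930, 1.24 ± 0.161, SE) and RPS26C (AT3G56340, 1.23 ± 0.144, SE). Both groups stem from words in the authors' titles and were chosen after the data were examined. Their camera adjusted p-values over 980 such words and word pairs were 1.26e-38 and 9.49e-32, with an adjusted p = 0.999 with an estimated correlation for both. Without wild-type replicate 3 the medians were 0.72 and 0.65. The rise was not confined to these wordings. Of all 315 probe sets titled ribosomal protein, 160 rose and 1 fell, and the chloroplast genes for S13 (0.93) and L21 (0.90) rose. Of 194 titled mitochondrial 13 rose and 3 fell (camera adjusted p = 2.74e-04). Of 176 titled chloroplast 18 rose and 2 fell (0.00123). Each of these wider words had an adjusted p = 0.999 with an estimated correlation. The median changes were 0.25 for mitochondrial and 0.20 for chloroplast titles. Over all probe sets they were 0.20 at log2 levels 4 to 6 and 0.14 at levels 6 to 8. Lists matched on brightness were not drawn for these 2 words, so their shift cannot be told apart from that of probe sets at middle levels.

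**Figure D3:**
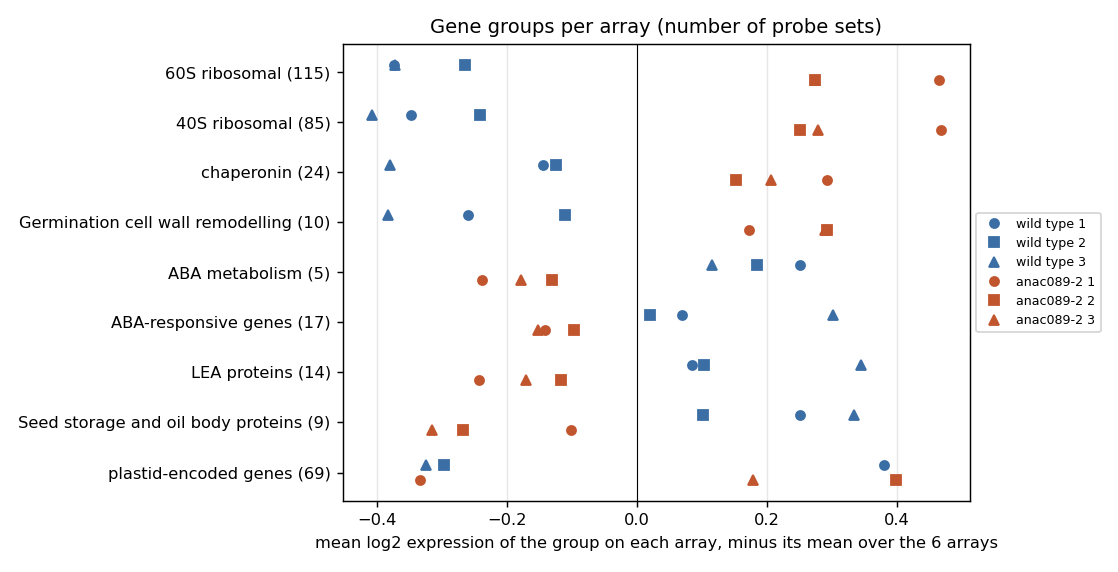
Mean log2 expression of gene groups on each array (wild type blue, anac089-2 red), relative to the group's mean over the 6 arrays, with the number of probe sets in parentheses. The 60S (115) and 40S (85) ribosomal groups and the cell wall list lie higher on all 3 anac089-2 arrays, the LEA, storage, ABA-responsive and ABA metabolism lists lie lower, and the plastid-encoded genes overlap.

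The remaining lists did not shift, though single members passed. In the redox and nitric oxide list (21 measured, camera adjusted p = 0.914), the glutathione transferase gene GSTF8 (-1.54 ± 0.219, SE) and the catalase gene CAT1 (-0.91 ± 0.107, SE) fell. The haemoglobin genes GLB2 (1.19 ± 0.196, SE) and GLB1 (0.45 ± 0.089, SE) rose, and adjusted over the list alone 5 members rose and 2 fell. In sugar and energy signalling (8 measured, 0.656), the dark-inducible genes SEN1 (-1.01) and ASN1 (-0.80) fell, and adjusted over the list alone 2 members fell and 1, DIN10, also dark-inducible and named after its value was seen, rose (0.69). In storage oil mobilisation (7 measured, 0.475), PXA1, the peroxisomal importer of fatty acids, fell (-0.63), and 2 fell when adjusted over the list alone. In pathogen defence (7 measured, 0.656), the salicylate synthesis gene ICS1 fell (-1.03), the 1 member that passed when adjusted over the list alone. In the unfolded protein response (12 measured, 0.703) SHD rose, and 3 members rose when adjusted over the list alone. In auxin response (12 measured, 0.914) GH3.5 rose (1.08), and among heat shock proteins (8 measured, 0.710) HSP23.6 rose (0.65), each the 1 member that passed when adjusted over the list alone. Of 55 named probe sets past the threshold, 3 lost their call whichever array was left out, HSP23.6 here and AT3G22490 and HIS1-3 above.

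Regulators of seed maturation and dormancy gave no member past the threshold (12 measured, camera adjusted p = 0.703, 0 adjusted over the list alone), with ABI3 at 0.50 and EEL at 0.39. The same held for cell cycle and DNA replication (7 measured, 0.656, 0 adjusted over the list alone), where PCNA2 had 0.62 and CDKA;1 0.59. In that list CYCD1;1, CYCD3;1, CYCB1;1, PCNA1 and MCM7 had mean levels under 4 in both groups. In ethylene synthesis and response (8 measured, 0.710), ERF1 had 0.70 and ERS1 0.48, and adjusted over the list alone 2 members rose and 1 fell. In flavonoid synthesis (9 measured, 0.210), CHI had -0.66 and UGT78D2 -0.59, and 1 member fell when adjusted over the list alone. Only 2 of the membrane-bound NAC genes were measured under a name found here, too few for a list test. ANAC014 had 0.48 (adjusted p = 0.0557) and ANAC091 0.02 (adjusted p = 0.971), and 1 passed when adjusted over the list alone. Besides the probe set with the largest fall, others titled NAM family protein passed, at -1.09, -0.99, -0.72 and 1.13. With 83 probe sets of this title, that share was close to the 1120 of 22746 over all probe sets. No source used here gives their genes.

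Marker lists for other tissues did not shift either, but most endosperm and seed coat markers had levels under 4 in both groups. At such levels only 30 of 11523 probe sets passed, so these lists could hardly show a change. Photosynthesis and greening genes (9 measured, camera adjusted p = 0.914) had GLK2 higher (0.63 ± 0.116, SE) and ELIP1 lower (-0.48), both also when adjusted over the list alone. LHCB5, PORA, PORB and PORC of that list also had mean levels under 4 in both groups. No marker passed, over all probe sets or adjusted over the list alone, for endosperm (3 measured, 0.914; FIS2 -0.20, FWA 0.20), seed coat (5 measured, 0.795; GL2 -0.24, TT2 0.09) or embryo tissue (6 measured, 0.914; PDF1 -0.65, FDH 0.57). Median, mean and test differed in sign for 5 lists. For heat shock proteins and auxin response the median (-0.03 and -0.05) and the test pointed down and the mean (0.05 and 0.11) up. For endosperm and embryo markers the test pointed down while median (0.13 and 0.08) and mean (0.04 and 0.03) were positive, and for seed coat markers the median was 0.05 and the mean -0.02 with the test down.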

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

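Cyclic loess was chosen after the results were seen; the other settings were fixed before. Of 18 alternatives for the count of 1120 probe sets, 6 stayed within 1.5 times it. The others gave 1701 (second quantile normalization), 1784 (cyclic loess), 2070 (array weights), 494 (replicate block), 1 (no moderation), 45 (adjusted p under 0.01) and 320 (a change of at least 1 on the log2 scale). With 1 array left out the count ran from 4 to 1667, and only the 1667, without wild-type replicate 3, lay within 1.5 times. The cause was not tested. No pairing by replicate number was seen in the residuals: same-numbered arrays had residual correlations of -0.089, -0.063 and -0.135, and 0 of 6 arrays correlated best with their own number. In the values themselves, wild-type replicate 2 and anac089-2 replicate 2 were each other's closest array of the other group (r = 0.9912). So few arrays cannot exclude a pairing. The share of higher calls was 59.7%. Scaling took it close to an even split, to 52.4% (quantile), 51.2% (median centring) and 50.6% (cyclic loess, 902 higher and 882 lower). The excess of higher calls therefore depended on the scaling. Lower calls outnumbered higher ones without anac089-2 replicate 1 (1 higher, 5 lower), 2 (213 and 257) or 3 (1 and 3), without moderation (0 and 1) and at an adjusted p under 0.01 (18 and 27). Median centring shifted all changes by -0.09.

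All 30 leading genes kept their direction in every setting. With the 6 arrays all passed at 0.05 except without moderation, where 1 passed, and 11 passed at 0.01. With 1 array left out 26, 22 and 30 passed without wild-type replicates 1, 2 and 3, and 3, 28 and 3 without anac089-2 replicates 1, 2 and 3. Of all 74 probe sets named by rule, 15 lost their call with the block, 54 without moderation, and 52 each without anac089-2 replicates 1 and 3. Of 37 title words, 37 lost theirs with an estimated correlation and 16 without wild-type replicate 3. ANAC091, never past the threshold, had -0.013 with quantile normalization, -0.073 with median centring, -0.166 with array weights, -0.046 with cyclic loess, and -0.198 to 0.157 with 1 array left out.

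The 5 shifted lists lost their call with an estimated correlation: adjusted p 0.440 for LEA proteins, storage proteins and ABA-responsive genes, 0.438 for ABA metabolism and germination cell wall. ABA-responsive genes gave 1.50e-04 to 0.0781 with 1 array left out, the highest without wild-type replicate 3, and the cell wall list 0.167 without the dimmest 40%. The block changed no list call. Lists that never passed changed sign in places. Adjusted p-values follow for each named setting in which the sign changed. Ranges with 1 array left out cover all such fits, of which only some changed the sign. Redox: 0.925 (quantile), 0.984 (trend), 0.952 (array weights), 0.881 (loess), 0.777 to 0.938 (1 array left out). Photosynthesis and greening: 0.962 (quantile), 0.954 (loess), 0.847 to 0.995. Heat shock: 0.892 (loess). Auxin: 0.985 (centring), 0.808 (without the dimmest 40%), 0.957 (robust), 0.846 to 0.938. Endosperm: 0.965 (quantile), 0.997 (loess), 0.814 to 0.938. Embryo: 0.985 (centring), 0.847 to 0.974. Where the filter on dim probe sets left under 3 members, a list was not tested. The alternatives planned for the ANAC089 transcript were not run, since no probe set was named for it.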

Other observations

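All tests in this part were chosen only after the results were seen, as were the title words and their narrower wordings. Several groups defined by title words shifted. Of 24 chaperonin probe sets 22 had positive values and 3 rose, among them the alpha subunit gene CCT1 (0.65 ± 0.119, SE; camera adjusted p = 2.88e-06). Of 23 elongation factor probe sets 5 rose, including eEF1Balpha2 (AT5G19510, 0.89 ± 0.113, SE; 7.41e-05). RNA-binding protein genes rose in 7 of 53 cases, GRP7 by 0.84 ± 0.138 (SE; 0.00970). Their median change was 0.16, near the 0.14 of all probe sets at log2 levels 6 to 8. On the lower side, 9 of 34 probe sets titled LEA fell (8.88e-06), with a median of -0.085 over the group. AT2G42560 fell by 1.45 and AT2G18340 by 1.23 on the log2 scale, while an LEA3 family gene, titled late embryogenesis abundant, rose by 1.47. The titled group shares 10 probe sets with the fixed LEA list, 3 of the 9 that fell included. Each of these 4 groups had an adjusted p = 0.999 with an estimated correlation.

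Camera also called 2 title groups of conjugating enzymes lower, though their medians were near 0 and the call rested on some members. Of 46 glutathione S-transferase probe sets 7 fell and 2 rose, GSTU22 at -1.68 ± 0.180 (SE; camera adjusted p = 0.0215). The median was -0.067, with 16 values positive and 30 negative. This call was lost without wild-type replicate 3 (0.120). Of 89 UDP-glucosyl transferase probe sets 9 fell and 1 rose, UGT76B1 at -1.10 ± 0.129 (SE; 0.0344, up to 0.282 with 1 array left out). The median was -0.037, with 39 values positive and 50 negative, and the replicate block ended this call (camera adjusted p = 0.0551). With an estimated correlation each had an adjusted p = 0.999. Genes encoded in the plastid differed between arrays within both groups: the mean over 69 of them was 6.92, 6.24 and 6.21 in wild type and 6.20, 6.94 and 6.72 in anac089-2.

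Too few splits of the 6 arrays exist, 10, for a share under 0.05. The real split gave 1120 probe sets and the highest other 0 (1 of 10 as large). For lists the real split gave 5 and the highest other 3 (1 of 10). For title words it gave 90 and the highest other, which sets wild-type replicate 1 and anac089-2 replicates 1 and 3 against the rest, 136 (2 of 10). The count of title words therefore does not set the real split apart, and the cause was not tested.

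The first pattern weighed is the rise of ribosomal protein genes, on average 0.67 over 200 probe sets. Wild-type replicate 3 alone is argued against, since the mean without it was 0.645, and so is the brightness of the probe sets, since the highest of 10000 random lists matched on brightness reached 0.064. A hypothesis is that the mutant seeds may be further along in germination. Of the 3 lists for cell cycle, greening and oil mobilisation, 0 were past the threshold and up. Of these, the cell cycle genes CYCD1;1, CYCD3;1, CYCB1;1, PCNA1 and MCM7 had mean levels under 4 in both groups. So did the greening genes LHCB5, PORA, PORB and PORC. At such levels 30 of 11523 probe sets passed, so these members could hardly show a rise. The cell wall list was up (camera adjusted p = 0.00253), and the LEA (7.09e-05), storage (1.45e-04) and ABA-responsive (0.00214) lists were down. None of them kept its call with an estimated correlation. The hypothesis stays open with 1 time point. An effect of ANAC089 itself is likewise open and was not tested.

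The second pattern is the fall of NIT4, whose gene lies next to ANAC089 in the RefSeq annotation of TAIR10.1. That 1 array decides it is argued against: the value nearest 0 with 1 array left out was -3.68. A chromosome segment that differs between the lines could contribute. Of 20 genes named and measured within 50 loci of ANAC089, NIT4 left out, 19 of them on one side, 3 or 15% passed, AT5G22320 (-0.93), the ribosomal protein gene AT5G22440 (1.27) and AT5G22460 (-0.73), against 4.25% elsewhere (one-sided Fisher's exact p = 0.0513). Without ribosomal protein genes 2 of 19 passed (exact p = 0.156), so a segment cannot be told apart from chance, and an effect of the mutated locus on its neighbour and regulation by ANAC089 both stay open with 1 mutant line.

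The third pattern is wild-type replicate 3, for which no biological explanation was tested: between log2 levels 4 and 6 its median deviation from the probe set means was -0.367, and its array weight was 0.208 against 0.883 to 1.80 for the others. An exchange with a mutant array is argued against by a test chosen after the correlations were seen: 0 of 3 mutant arrays correlated better with wild-type replicates 1 and 2 than with the other mutant arrays, though a wrong label or an exchange with an outside sample would need no such partner. An earlier test alone had left it open: of the probe sets called by the 5 other arrays, replicate 3 lay nearer the other wild-type arrays on 97.1% of the 910 higher and 69.6% of the 757 lower in anac089-2, with more than 90% asked of both. Degraded RNA stays open, since 1 of 3 control genes, actin, had its highest 3-prime minus 5-prime difference there. A second actin pair did not: it read 11.42 and 10.69 there, against 11.70 and 10.80 on anac089-2 replicate 1. A brightness-dependent shift left by the normalization could account for part: its mean correlation with its group went from 0.982 to 0.985 with cyclic loess and stayed the lowest.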
